A study of Mus musculus with 15 samples.

How the data were processed

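Gene expression in cells of C57Bl/6 mice was measured on 15 one-colour Affymetrix 3' expression arrays. The deposited values are intensities on a linear scale, 1 value per probe set and array. How the authors corrected background, summarised probes and scaled the arrays is not given in the sources used here. The values show 4 scales: 1 for the 8 bone marrow progenitor arrays, 1 for the 3 culture arrays, 1 for the 3 monocyte arrays, and 1 for the single pre-cDC array titled Spl. Differences were therefore formed within the progenitor, culture or monocyte arrays, and the Spl array was compared with the bone marrow pre-cDC arrays with its shift stated beside it. Precision is limited by the number of arrays, which is 2 for each bone marrow progenitor group and 1 for each other group.

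The groups, per the labels, were common myeloid progenitors (CMP), granulocyte-macrophage progenitors (GMP), common dendritic cell progenitors (CDP) and precursors of classical dendritic cells (pre-cDC) from bone marrow, 2 arrays each. Single arrays covered a pre-cDC sample titled Spl, adherent and non-adherent CD11c+ cells of bone marrow grown for 7 days with GM-CSF at 20 ng/ml, adherent cells grown for 7 days with M-CSF at 20 ng/ml, and bone marrow monocytes given GM-CSF at 20 ng/ml for 0, 24 or 48 h. Columns were matched to samples by their identifiers, and 0 columns were left without a sample.

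Of 45037 probe sets, 34945 were annotated with 1 gene, 932 with several and 9160 with none; only the first class was used. Each of the 18194 genes was represented by its probe set with the highest mean over all 15 arrays, and 9185 genes had 1 probe set. Of the genes, 18032 were matched to the symbols of the reference annotation. Probe sets without a single gene (10092) were tested apart, and 631, 253, 1783 and 1202 of them were called in GMP against CMP, CDP against CMP, CDP against GMP and pre-cDC against CDP; they are not named.

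Values were transformed as log2(intensity + 32), so a log2 difference against a dim value depends on the added 32. The 4 tested comparisons came from 1 limma fit (limma 3.58.1 in R 4.3.3; lmFit, contrasts.fit, eBayes with an intensity trend) to the 8 bone marrow progenitor arrays in 4 groups, with 4 residual degrees of freedom and 12.6 after moderation. Tests were two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Genes particular to bone marrow pre-cDC had to pass that threshold and differ at least 2-fold, in the same direction, from each of CMP, GMP and CDP. Comparisons with a single array have no p-value: a gene was counted when it differed at least 4-fold and its higher value lay above the median of all probe sets on that array. For the Spl array the gene also had to lie beyond both bone marrow pre-cDC arrays. Tables were handled with matrixStats 1.5.0 and data.table (version 1.17.8), and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

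There were 25 gene lists of cell types and pathways and 6 lists of markers of other cells, 31 in all, written from textbook knowledge. Flt3, Kit and Itgax, genes of markers used in the sorts, belong to the classical dendritic cell core list. Flt3 and Kit also belong to the cytokine receptor list. Calls of these lists between sorted groups therefore draw in part on the gates. Irf4, Mgl2, Clec10a and Ccl17 belong to both the cDC2 and the alternative activation list. Ccl17, Ccl22 and Pdcd1lg2 belong to both the alternative activation and the costimulation list. Shifts of these lists are therefore not independent of each other in any comparison. Of the 466 symbols in the lists and a panel of 32 genes, 427 were matched, including 30 of the panel. In tested comparisons the lists were tested with camera from limma at an inter-gene correlation of 0.01, adjusted over the 31 lists of a comparison, and again with an estimated correlation. With an estimated correlation camera also limits its test to the 4 residual degrees of freedom of the fit, which it does not do at a preset correlation. The 2 settings therefore differ in more than the correlation, and the second is no check of correlation alone. In single-array comparisons the median difference of a list was placed among 10000 random lists of the same size, matched on mean expression in 20 bins; a list counts as outside when it lies below the 2.5th percentile or as far into the upper end. Such percentiles describe these arrays and are not p-values.

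Genes were named by a rule: the 8 largest rises and 8 largest falls past the threshold, with no overlap between the arrays of the groups compared and a higher group mean above the median of all probe sets; up to 3 members of each list called by camera; and the panel. In single-array comparisons the rule took the 8 largest differences in each direction among the genes counted, up to 3 members of each outside list, and the panel. RIKEN clones, expressed sequences, LOC and Gm models, XIST and Y-linked genes and antibody segments were passed over, and some names are left out for length. The groups, comparisons, tests, gene lists, naming rule and alternatives were fixed before the data were examined. Tests of cell cycle classes, of single erythroid genes and of culture genes in monocytes were added after the results were seen.

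On simulated arrays with the layout of GMP against CMP and 18194 genes, the same fit found 100% of 100 genes changed 2-fold and 100% of 100 genes changed 4-fold, and called 13 unchanged genes. It called 0 genes where nothing was changed, found the planted list, and called 0 of 30 unchanged lists. Noise was drawn independently for each gene there, so the simulation does not probe lists of correlated genes. The estimated correlation of the measured lists reached 0.43, for the erythroid markers.

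The alternatives tried were quantile normalization, centring each array on its median, pseudocounts of 1 and 128, every probe set on its own, the mean of a gene's probe sets, a filter on dim genes, eBayes without a trend, all 15 arrays or only the 4 compared in the fit, the sample number as a replicate block, leaving out each array, a 2-fold minimum, no floor or a floor at the 75th percentile in single-array comparisons, and a limma fit that includes the Spl array. Values of the culture and monocyte arrays were not compared directly with each other or with the progenitors, because their scales differ. No raw array files were analysed here.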

Results

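Expression was measured in sorted myeloid progenitors, in bone marrow cultures and in monocytes of C57Bl/6 mice on 15 arrays. CMP, GMP, CDP and bone marrow pre-cDC had 2 arrays each, and the 7 other samples had 1 array each. Per the labels, CMP and CDP were both CD135+ and CD16/32-, with high and intermediate CD117. Pre-cDC were CD117 low, CD135+ and CD11c+, and GMP were CD117 high, CD16/32+ and CD135-. The median intensity of an array was 15.95 to 17.44 in the bone marrow progenitors, 24.1 to 25.7 in the cultures, 77.7 to 80.5 in the monocytes and 74.2 on the Spl array. Between the 2 arrays of a progenitor group the log2 values correlated across genes at 0.995 to 0.997, 2 to 9 genes differed 2-fold, and 0 genes differed 4-fold. The labels do not say that these arrays came from separate animals, so the p-values measure only the spread between these samples.

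**Figure D1:**
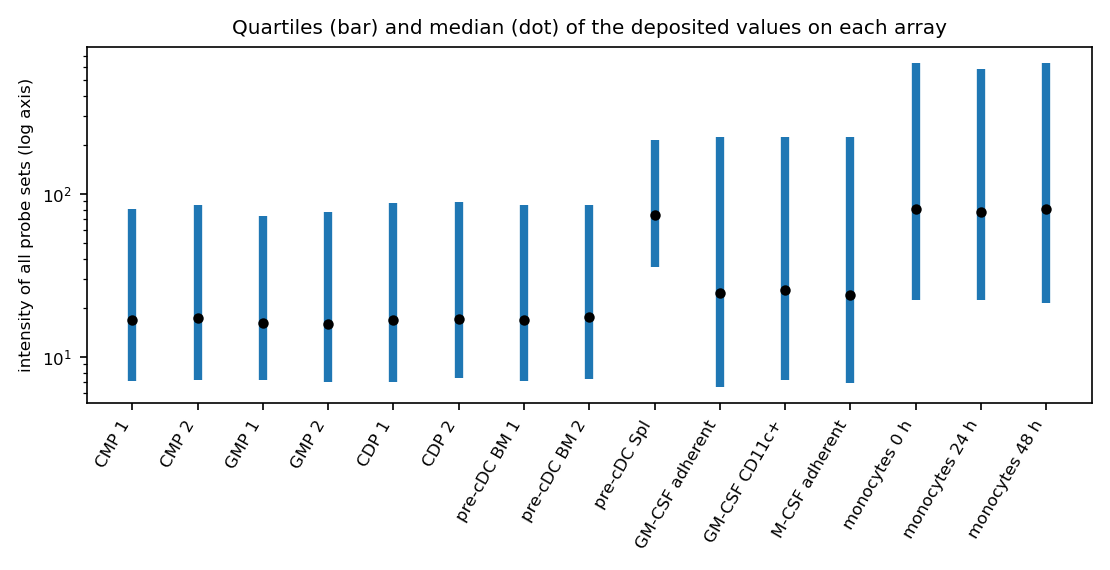
Intensity of all probe sets on each of the 15 arrays, on a log scale, with the median and the quartiles. The medians lie at 15.95 to 17.44 for the 8 bone marrow progenitor arrays, at 24.1 to 25.7 for the cultures, at 77.7 to 80.5 for the monocytes and at 74.2 for the Spl array.

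All measured genes of the primary granule list, and part of those of the secondary granule list, rose from CMP to GMP. Elane, the gene of neutrophil elastase, read 3653 ± 83.6 in GMP and 125 ± 9.69 in CMP (mean intensity ± SD, n = 2 arrays each), a log2 difference of 4.55 (SE 0.117, adjusted p = 5.75e-11). Ms4a3, a membrane protein gene of granulocyte and monocyte progenitors, rose from 112 ± 6.56 to 3402 ± 23.5 (log2 difference 4.58, SE 0.103, adjusted p = 2.55e-11). S100a8, which encodes a calcium-binding protein abundant in neutrophils, rose from 34.5 ± 12.7 to 2156 ± 193 (5.05, SE 0.226, adjusted p = 7.94e-09). The transcription factor genes Gfi1 and Cebpa, both needed for granulocyte development, rose by 1.91 and 0.87 on the log2 scale (SE 0.106 and 0.13, adjusted p = 7.02e-08 and 0.000375).

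All 14 measured genes of the primary granule and granulocyte commitment list rose in GMP (median log2 difference 1.67, camera adjusted p = 4.45e-22, adjusted p = 0.0741 with an estimated correlation). Of 13 secondary granule genes 8 rose and 1 fell (median 0.57, adjusted p = 6.69e-07, and 0.0741 as adjusted p with an estimated correlation). Glycolysis genes also rose, 11 of 18 with none falling, among them the phosphofructokinase gene Pfkp (1.08, SE 0.107); the list had a median of 0.43 and an adjusted p of 6.69e-07, with adjusted p = 0.148 with an estimated correlation. Of 16 lysosome genes 7 rose and 0 fell (median 0.26, adjusted p = 9.31e-05, adjusted p = 0.0896 with an estimated correlation). Of 31 cell cycle genes 5 rose and 0 fell, among them the ribonucleotide reductase gene Rrm2 (0.62, SE 0.0989); the list's adjusted p was 0.0123, and adjusted p = 0.542 with an estimated correlation. Adjusted over the list alone, 8 cell cycle genes rose and 1 fell, and 8 lysosome genes rose and 2 fell. Markers of mast cells, basophils and eosinophils moved with these groups: 4 of 7 rose, including the mast cell carboxypeptidase gene Cpa3 (205 ± 71.5 against 44.5 ± 6.1), with an adjusted p of 0.00155 and adjusted p = 0.172 with an estimated correlation.

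Genes of early progenitors and several lists of the dendritic cell lineage were lower in GMP than in CMP. Of 19 early progenitor genes 16 fell and 1 rose, or 17 and 1 adjusted over the list alone (median -0.83, adjusted p = 3.55e-11, adjusted p = 0.0896 with an estimated correlation); Meis1 and Hoxa9, homeobox genes of stem and progenitor cells, fell by 1.84 and 1.72 (SE 0.119 and 0.142). Of 24 classical dendritic cell core genes 11 fell and 0 rose (13 adjusted over the list alone; adjusted p = 6.19e-06, and adjusted p = 0.0896 with an estimated correlation). Of 10 MHC class II genes 7 fell (9 adjusted over the list alone; median -1.04, adjusted p = 1.89e-06, adjusted p = 0.0896 with an estimated correlation), and Cd74, the gene of the invariant chain, read 11.3 ± 0.318 in GMP and 118 ± 79.8 in CMP. Of 13 plasmacytoid dendritic cell genes 6 fell (adjusted p = 0.000403, adjusted p = 0.106 with an estimated correlation), including Tcf4, a transcription factor gene of that lineage (-1.64, SE 0.0987). The cDC1 and cDC2 lists were not called: 2 of 13 cDC1 genes fell and 0 rose (adjusted p = 0.685), and of 12 cDC2 genes 3 rose and 2 fell (adjusted p = 0.446). Irf8, a transcription factor gene of monocyte and dendritic cell development, read 1561 ± 5.99 in GMP and 2033 ± 108 in CMP (-0.37, SE 0.0756, adjusted p = 0.00369; adjusted p = 0.0596 when CMP replicate 2 was left out).

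In GMP 10 of 19 immediate early genes also fell (median -0.41, adjusted p = 9.31e-05, adjusted p = 0.207 with an estimated correlation), as did 9 of 16 interferon response genes while 1 rose (median -0.45, adjusted p = 6.19e-06, adjusted p = 0.137 with an estimated correlation). Of 16 chemokine receptor and homing genes 5 fell and of 11 STAT5 and cytokine feedback genes 5 fell; both lists had an adjusted p of 0.00786, with adjusted p = 0.137 and 0.165 with an estimated correlation. Adjusted over the list alone, 12 immediate early, 12 interferon response, 7 chemokine receptor, 6 STAT5 and 8 plasmacytoid genes fell. On that basis 1 interferon response gene rose, and 11 glycolysis genes rose while 1 fell. Over all genes 3075 of 18194 were called, 1281 higher and 1794 lower in GMP, and 406 of them differed at least 2-fold. The count fell whichever CMP or GMP array was left out. Leaving one out keeps 1 array in that group, so the fall does not show that the count rests on a particular array. None of the 14 lists called in this comparison kept its call with an estimated correlation. The secondary granule and lysosome lists lost theirs at estimated correlations of -0.0082 and -0.0257, below the preset 0.01. Correlated genes therefore do not explain every loss. That setting also leaves the test only 4 degrees of freedom, which by itself raises the p-values.

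CDP were set against CMP, from which they differ by sort in the level of CD117. Klf4, a transcription factor gene of monocytes and dendritic cells, rose from 131 ± 6.52 in CMP to 1340.5 ± 61.2 in CDP (log2 difference 3.08, SE 0.113, adjusted p = 2.43e-08). Id2, which encodes an inhibitor of basic helix-loop-helix factors needed by several dendritic cell types, rose from 44.2 ± 5.58 to 465 ± 61.8 (2.70, SE 0.118, adjusted p = 2.97e-08). Irf8 rose from 2033 ± 108 to 4713 ± 315 (1.1995, SE 0.0756, adjusted p = 5.62e-07), and Batf3, a transcription factor gene of the cDC1 lineage, from 4.62 ± 0.608 to 44.0 ± 6.94 (1.05, SE 0.0924). The transcription factor gene Nfil3 rose from 45.97 ± 0.163 to 439.8 ± 13.9 (adjusted p = 2.97e-08), and Zbtb46, a marker gene of classical dendritic cells, stayed dim at 27.8 ± 8.9 against 23.9 ± 11.2 (adjusted p = 0.736).

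Antigen presentation and dendritic cell lists rose together in CDP. Of 10 MHC class II genes 9 rose (median 0.94, adjusted p = 4.61e-10, adjusted p = 0.0756 with an estimated correlation), H2-Aa from 96.6 ± 33.7 to 678 ± 118. Of 24 classical dendritic cell core genes 14 rose and 1 fell (adjusted p = 2.24e-06, adjusted p = 0.0756 with an estimated correlation); Mycl, a Myc family gene active in dendritic cells, rose by 2.14 (SE 0.109). Of 13 cDC1 genes 5 rose and 0 fell, of 12 cDC2 genes 5 rose and 1 fell, and of 13 plasmacytoid genes 7 rose and 0 fell (adjusted p = 0.000367, 0.000421 and 2.55e-05; each list had adjusted p = 0.0756 with an estimated correlation). Adjusted over the list alone, 15 core genes rose and 3 fell, and 7 cDC2 genes rose and 1 fell. Of 17 monocyte genes 11 rose and 0 fell (median 0.78, adjusted p = 9.82e-11, adjusted p = 0.116 with an estimated correlation), including the fractalkine receptor gene Cx3cr1, from 138 ± 11.1 to 628 ± 38.5. Chemokine receptor and homing genes rose in 7 of 16 cases and fell in 1, led by the integrin gene Itgb7 (2.44, SE 0.11; list adjusted p = 1.44e-05, adjusted p = 0.0756 with an estimated correlation).

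Lineage transcription factors rose in 12 of 29 cases and fell in 4 (adjusted p = 0.000125, adjusted p = 0.11 with an estimated correlation), and of 17 cytokine receptor genes 11 rose and 5 fell (adjusted p = 0.00874, adjusted p = 0.116 with an estimated correlation). The receptor genes that rose included Csf2rb2 (1.61, SE 0.12), and Kit, the CD117 gene on which the sort was gated, fell by 1.71. Of 31 cell cycle genes 14 rose and 0 fell (18 adjusted over the list alone; median 0.31, adjusted p = 4.17e-08, adjusted p = 0.135 with an estimated correlation). Immediate early genes rose in 10 of 19 cases and fell in 1, such as the AP-1 gene Fosb (1.19, SE 0.121; list adjusted p = 8.03e-06, adjusted p = 0.135 with an estimated correlation). Lysosome genes rose in 6 of 16 cases and fell in 2 (adjusted p = 0.00916, adjusted p = 0.116 with an estimated correlation), with the cathepsin gene Ctsb at 1746 ± 111 against 953 ± 3.93. Adjusted over the list alone, 14 immediate early genes rose and 1 fell, 9 lysosome genes rose and 3 fell, 12 monocyte genes rose, 7 plasmacytoid genes rose and 1 fell, and 3 interferon response genes rose and 9 fell.

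The early progenitor list fell in CDP, with 15 of 19 genes lower and 0 higher (median -0.78, adjusted p = 8.18e-11, adjusted p = 0.0756 with an estimated correlation). Primary granule genes fell in 8 of 14 cases (adjusted p = 4.68e-06, adjusted p = 0.116 with an estimated correlation), and ribosome biogenesis and Myc genes in 9 of 16, or 12 adjusted over the list alone (adjusted p = 1.58e-07, adjusted p = 0.135 with an estimated correlation). Myc itself, a driver of cell growth, fell by 0.99 (SE 0.141, adjusted p = 0.000384). Glycolysis genes fell in 7 of 18 cases and rose in 1, interferon response genes fell in 7 of 16 and rose in 3, and lipid handling genes fell in 2 of 14. Their adjusted p values were 0.00403, 0.0142 and 0.0346, and adjusted p = 0.296, 0.294 and 0.135 with an estimated correlation.

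Erythroid markers moved with this comparison: 5 of 8 fell in CDP and 0 rose (median -2.26, adjusted p = 5.63e-06, adjusted p = 0.135 with an estimated correlation). Car1 and Car2, carbonic anhydrase genes of red cell precursors, read 1712 ± 258 and 2515 ± 419 in CMP and 16.4 ± 7.91 and 131 ± 27.3 in CDP. Klf1, the gene of an erythroid transcription factor, fell by 2.93 (SE 0.302). Over all genes 2611 were called, 1388 higher and 1223 lower in CDP, and 312 of them differed at least 2-fold. The count was 1602 without CMP replicate 1 and 1656 without CMP replicate 2, and none of the 19 called lists kept its call with an estimated correlation.

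CDP differed more from GMP than from CMP by the number of genes called, a difference that was not tested. Ms4a3 fell from 3402 ± 23.5 in GMP to 44.8 ± 1.81 in CDP (log2 difference -5.48, SE 0.103, adjusted p = 5.26e-12), and Elane from 3653 ± 83.6 to 58.1 ± 12.6 (-5.36, SE 0.117). Cd74 rose from 11.3 ± 0.318 to 863 ± 191 (4.35, SE 0.262, adjusted p = 6.52e-08), and Itgb7 from 36.8 ± 0.82 to 862 ± 88.4 (3.69, SE 0.11). Irf8 stood at 4713 ± 315 in CDP and 1561 ± 5.99 in GMP (1.57, SE 0.0756), and Gfi1 at 50.5 ± 1.23 and 564 ± 29.9 (-2.85, SE 0.106). Flt3 (4.55) and Fcgr3 (-5.04) differed as the CD135 and CD16/32 gates require. Flt3 is also a member of the classical dendritic cell core and cytokine receptor lists.

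Of the lists, 6 kept their call with an estimated correlation, each at adjusted p = 0.0466: primary granule (0 of 14 rose, 14 fell, median -1.91, adjusted p = 2.88e-18 at the preset correlation), secondary granule (1 of 13 rose, 9 fell, 2.39e-05), MHC class II (10 of 10 rose, median 2.20, 1.49e-10), classical dendritic cell core (16 of 24 rose, 1 fell, 3.76e-08), plasmacytoid (11 of 13 rose, 0 fell, 3.28e-07) and chemokine receptors and homing (11 of 16 rose, 1 fell, 1.29e-05). Monocyte genes rose in 11 of 17 cases and fell in 2 (median 0.98, adjusted p = 0.000199, adjusted p = 0.277 with an estimated correlation). Of 13 cDC1 genes 5 rose (adjusted p = 0.00623, adjusted p = 0.133 with an estimated correlation). Of 12 cDC2 genes 7 rose and 1 fell (adjusted p = 0.0301, adjusted p = 0.155 with an estimated correlation); the lectin gene Mgl2 was the one that fell, by 1.83 (SE 0.0852).

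Immediate early genes rose in 13 of 19 cases and fell in 1 (median 0.73, adjusted p = 4.49e-07, adjusted p = 0.141 with an estimated correlation), and Egr1, a growth-response transcription factor gene, rose by 2.09 (SE 0.177). Lineage transcription factors rose in 17 of 29 cases and fell in 7, and cytokine receptors rose in 9 of 17 and fell in 4 (adjusted p = 0.00103 and 0.0122, each with adjusted p = 0.141 with an estimated correlation). STAT5 and cytokine feedback genes rose in 6 of 11 cases, including the kinase gene Pim1 (1.18, SE 0.14; list adjusted p = 0.00623, adjusted p = 0.147 with an estimated correlation). Cell cycle genes rose in 11 of 31 cases and fell in 1, including the proliferation marker gene Mki67 (0.58, SE 0.0837; list adjusted p = 0.0367, adjusted p = 0.508 with an estimated correlation). Glycolysis genes fell in 15 of 18 cases (median -0.63, adjusted p = 3.39e-09, adjusted p = 0.133 with an estimated correlation), and ribosome biogenesis genes in 13 of 16 (median -0.47, adjusted p = 1.41e-06, adjusted p = 0.19 with an estimated correlation). Adjusted over the list alone, 16 immediate early genes rose and 2 fell, 12 cell cycle genes rose and 2 fell, 10 cytokine receptor genes rose and 4 fell, 7 STAT5 genes rose, 11 monocyte genes rose and 3 fell, 7 cDC2 genes rose and 2 fell, 11 plasmacytoid genes rose and 1 fell, and 14 ribosome biogenesis genes fell.

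Markers of other cells moved here too. Of 8 erythroid markers 5 fell in CDP (median -1.78, adjusted p = 0.00103, adjusted p = 0.272 with an estimated correlation), and of 7 mast cell, basophil and eosinophil markers 4 fell (median -0.77, adjusted p = 0.00235, adjusted p = 0.167 with an estimated correlation). Over all genes 5115 were called, 2911 higher and 2204 lower in CDP, and 798 of them differed at least 2-fold.

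Bone marrow pre-cDC were set against CDP, taken here as the stage before them. Cd209a, a lectin gene of cDC2 and monocyte-derived cells, rose from 31.3 ± 6.84 in CDP to 2622 ± 18.9 in pre-cDC (log2 difference 5.39, SE 0.11, adjusted p = 5.08e-12). Spib, the gene of an Ets factor, rose from 30.4 ± 1.24 to 1549 ± 35.0 (4.66, SE 0.0974, adjusted p = 5.08e-12). Zbtb46 rose from 27.8 ± 8.9 to 402 ± 27.8 (2.87, SE 0.145, adjusted p = 1.04e-08), and Irf4, a transcription factor gene of cDC2, from 11.8 ± 1.98 to 397 ± 56.9 (3.28, SE 0.106, adjusted p = 2.27e-10). Mpo, the myeloperoxidase gene, fell from 4543 ± 593 to 18.4 ± 2.33 (-6.50, SE 0.0931, adjusted p = 1.74e-13), and Cd34, a surface marker gene of progenitors, from 1503 ± 67.5 to 52.9 ± 14.96 (-4.19, SE 0.117). Irf8 had the values 5229 ± 338 and 4713 ± 315, a difference that did not pass the test (adjusted p = 0.161), and Id2 fell by 1.44 (SE 0.118).

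Of 10 MHC class II genes 9 rose in pre-cDC and 1 fell (median 1.58, adjusted p = 7.27e-07, adjusted p = 0.139 with an estimated correlation); H2-Aa rose from 678 ± 118 to 5260.3 ± 502, and Ciita, the transactivator gene of that pathway, from 16.7 ± 1.65 to 149.7 ± 13.01. Of 12 cDC2 genes 9 rose and 0 fell (median 1.02, adjusted p = 1.98e-07, adjusted p = 0.13 with an estimated correlation). Classical dendritic cell core genes rose in 13 of 24 cases and fell in 5, and plasmacytoid genes rose in 8 of 13 and fell in 4 (adjusted p = 0.000358 and 0.00624, each with adjusted p = 0.139 with an estimated correlation). Of 13 cDC1 genes 3 rose and 3 fell (adjusted p = 0.588). Monocyte genes rose in 12 of 17 cases and fell in 1, or 12 and 3 adjusted over the list alone (adjusted p = 2.32e-05, adjusted p = 0.24 with an estimated correlation), with Klf4 at 5397 ± 503 against 1340.5 ± 61.2. Macrophage genes rose in 8 of 19 cases and fell in 2, among them the scavenger receptor gene Cd68 (2.49, SE 0.118; list adjusted p = 0.0397, adjusted p = 0.246 with an estimated correlation).

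Interferon response genes rose in 10 of 16 cases and fell in 1 (12 and 1 adjusted over the list alone; median 0.62, adjusted p = 2.19e-06, adjusted p = 0.139 with an estimated correlation), led by Irf7, a regulator of interferon genes (2.30, SE 0.133). Immediate early genes rose in 16 of 19 cases and fell in 1, with the stress-response gene Atf3 at 1042 ± 54.9 against 40.8 ± 22.1 (list median 1.03, adjusted p = 1.75e-08, adjusted p = 0.139 with an estimated correlation). Lineage transcription factors rose in 15 of 29 cases and fell in 5 (adjusted p = 0.00165, adjusted p = 0.139 with an estimated correlation). Cholesterol synthesis genes rose in 8 of 16 cases, including Hmgcs1 (1.06, SE 0.116; list adjusted p = 0.00585, adjusted p = 0.243 with an estimated correlation). Lysosome genes rose in 10 of 16 cases and fell in 1 (adjusted p = 0.0134, adjusted p = 0.139 with an estimated correlation), and alternative activation genes rose in 3 of 12 (adjusted p = 0.0397, adjusted p = 0.184 with an estimated correlation). The alternative activation genes that rose include Irf4 (3.28) and Clec10a (1.85), which also belong to the cDC2 list. Adjusted over the list alone, 17 immediate early genes rose and 1 fell, 11 lysosome genes rose and 2 fell, and 14 classical dendritic cell core genes rose and 5 fell.

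Ribosome biogenesis and Myc genes fell in 15 of 16 cases in pre-cDC (median -1.24, adjusted p = 2.84e-09, adjusted p = 0.139 with an estimated correlation), Myc itself by 1.85 (SE 0.141). Early progenitor genes fell in 14 of 19 cases, the homeobox gene Hoxa9 by 3.14 (list adjusted p = 5.85e-08, adjusted p = 0.139 with an estimated correlation). Primary granule genes fell in 10 of 14 cases and rose in 2 (adjusted p = 3.88e-06, adjusted p = 0.139 with an estimated correlation). Glycolysis genes fell in 10 of 18 cases and rose in 3, with the triosephosphate isomerase gene Tpi1 at 422 ± 87.3 against 1505 ± 59.8 (list adjusted p = 0.00585, adjusted p = 0.301 with an estimated correlation). Of 31 cell cycle genes 15 rose and 13 fell; the median was 0.11, the mean -0.10, and the test, which pointed down, was not passed (adjusted p = 0.801).

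Over all genes 6073 were called between pre-cDC and CDP, 2626 higher and 3447 lower in pre-cDC, and 1185 of them differed at least 2-fold. In none of the 4 comparisons did camera call the lists of costimulation and maturation, inflammatory cytokines, megakaryocyte, B cell, T and NK cell or stromal markers; their lowest adjusted p values were 0.119, 0.211, 0.125, 0.211, 0.284 and 0.258. Median, mean and test did not all share a sign, always without a call, for the monocyte, macrophage, cholesterol synthesis and megakaryocyte lists in GMP against CMP and the macrophage, costimulation, STAT5 and B cell lists in CDP against CMP. The same held for the macrophage, inflammatory cytokine and stromal lists in CDP against GMP and for the cell cycle and stromal lists in pre-cDC against CDP.

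**Figure D2:**
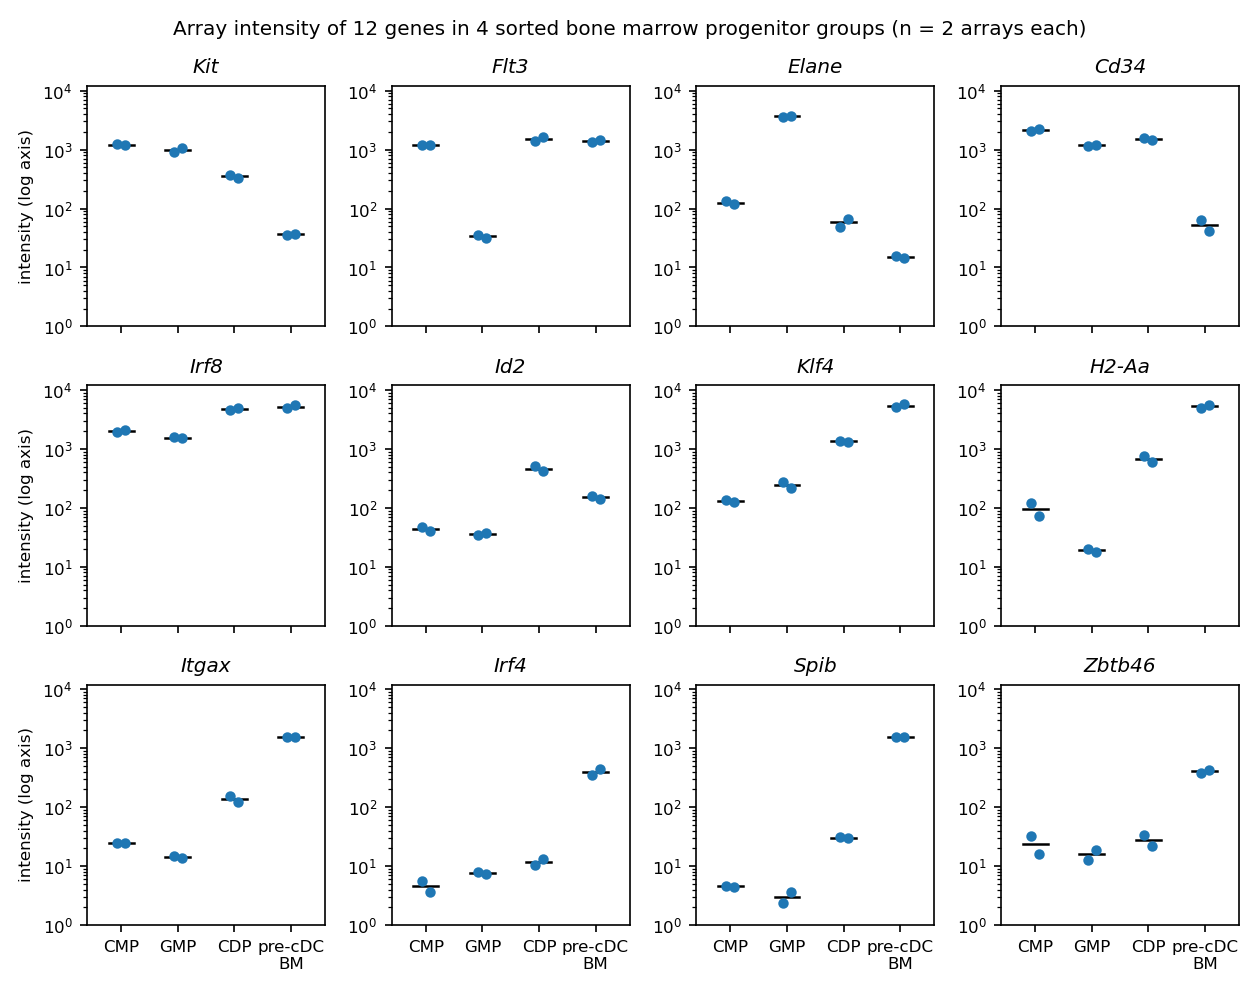
Intensity on a log axis of 12 genes in CMP, GMP, CDP and bone marrow pre-cDC, where each dot is an array and each line the mean of 2 arrays. Zbtb46 lies at 23.9, 15.8 and 27.8 in CMP, GMP and CDP and at 402 in pre-cDC, Irf8 is already at 4713 in CDP, and Elane is highest in GMP at 3653.

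**Figure D3:**
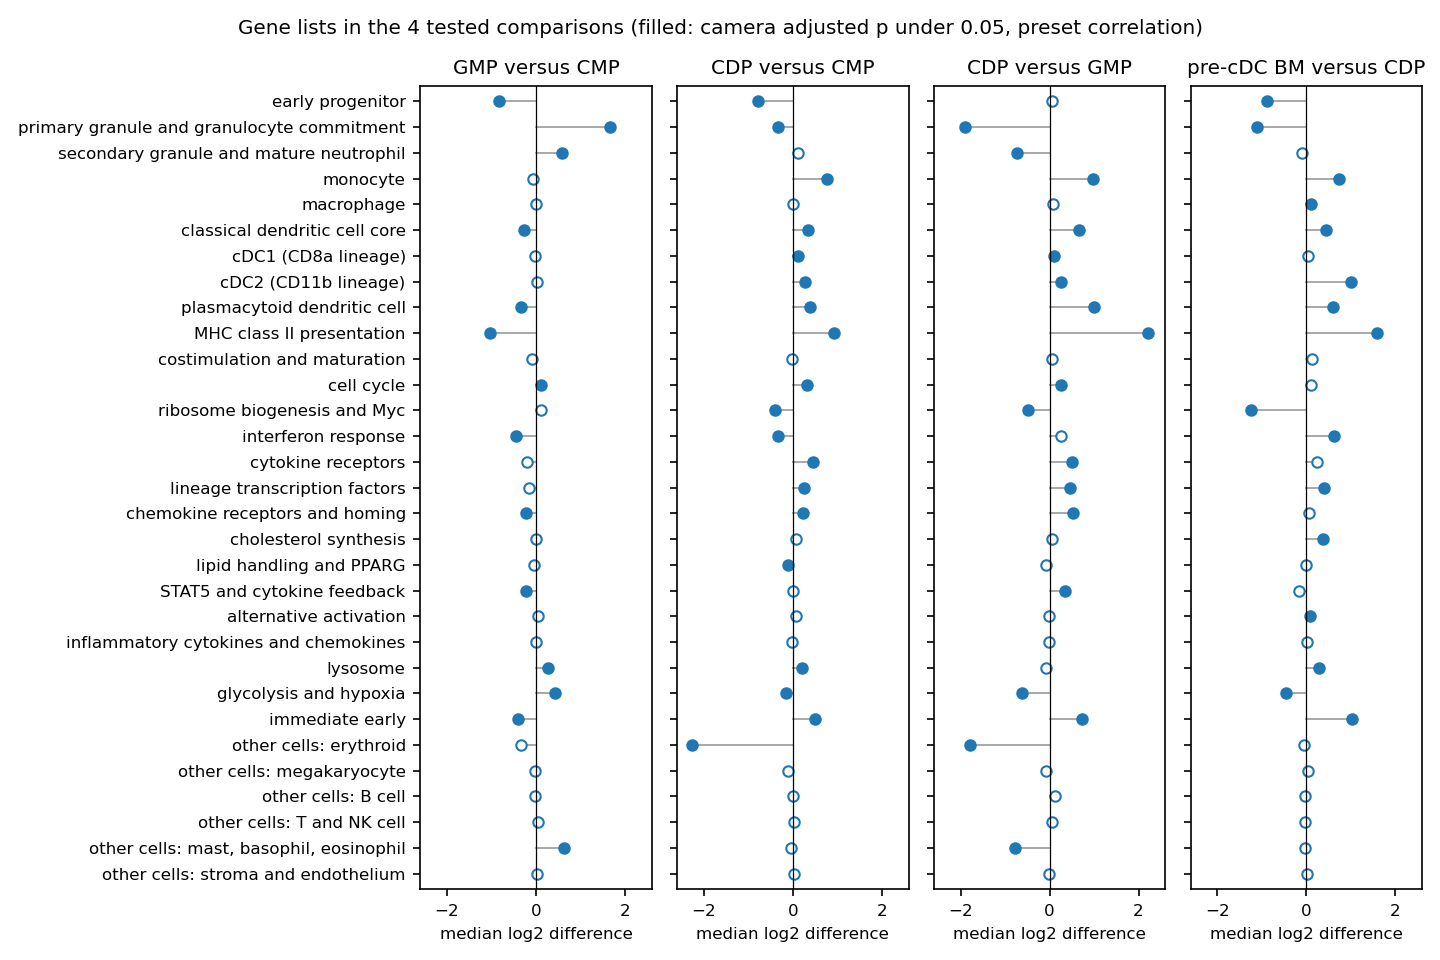
Median log2 difference of 31 gene lists in the 4 tested comparisons, with filled points for lists called by camera at the preset correlation. MHC class II has medians of -1.04 in GMP against CMP, 0.94 in CDP against CMP, 2.20 in CDP against GMP and 1.58 in pre-cDC against CDP, and ribosome biogenesis lies at -1.24 in the last.

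A set of 965 genes separated bone marrow pre-cDC from all 3 earlier progenitors at least 2-fold, 535 higher and 430 lower. The size of the set depends on the pseudocount, with 1768 genes at the lower and 470 at the higher alternative. It was 683 with the mean of a gene's probe sets and 1271 with quantile normalization. Among the genes higher in pre-cDC, Zbtb46 exceeded CMP, GMP and CDP by 2.97, 3.19 and 2.87 on the log2 scale, Irf4 by 3.54, 3.43 and 3.28, and Cd209a by 6.11, 6.19 and 5.39. Csf2ra, the gene of the GM-CSF receptor alpha chain, exceeded them by 2.45, 1.52 and 1.56, and Slamf7, a surface receptor gene of leukocytes, by 5.09, 5.12 and 4.12. Among the genes lower in pre-cDC, Mpo differed by -6.71, -7.42 and -6.50, Cd34 by -4.68, -3.85 and -4.19, and Myc by -2.84, -2.30 and -1.85. If the 3 lists of differences were independent, chance would put 2.44 higher and 2.41 lower genes in all 3. The 3 comparisons share the pre-cDC arrays, so their lists are not independent and the real chance count is not known from this figure. On simulated arrays without change 0 genes met the criteria, but noise there was drawn independently for each gene.

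The single pre-cDC array titled Spl was set against the bone marrow pre-cDC arrays; its title and its cell type field differ, since the latter names bone marrow. No comparison with a single array has a replicate check. All genes together lay 0.81 higher on this array at the median (log2), so gene differences are given after subtraction of 0.81. Il1b, the gene of an inflammatory cytokine, read 5476 on this array and 15.8 in bone marrow pre-cDC, a difference of 6.04. The maturation marker gene Cd83 read 4741 against 15.1 (5.86), the costimulatory ligand gene Cd86 1519.6 against 30.1 (3.84), and the chemokine receptor gene Ccr7 408 against 6.01 (2.72). Cell cycle genes were far lower: Cdk1, the mitotic kinase gene, read 71.8 against 1632 (-4.81), and the cyclin gene Ccna2 113 against 1969 (-4.60). Irf8 read 568 against 5229 (-3.94), F13a1, the gene of coagulation factor XIII A, 65.5 against 2419 (-5.46), and Zbtb46 1083 against 402 (0.55). Kit read 1105 against 36.5 (3.24), although the gate for pre-cDC in the labels is low CD117.

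List medians and 4-fold counts, unlike the gene differences, are given before the subtraction of 0.81. The cell cycle list had a median difference of -2.62 before subtraction, below all 10000 random lists, with 18 of 31 genes at least 4-fold lower. Its median was -3.75 after quantile normalization and -3.74 after median centring, with 24 such genes under each. It was -1.43 with 10 such genes when the probe sets of a gene were averaged, still below all random lists. The costimulation and maturation list had a median of 2.32, above all random lists, with 13 of 20 genes at least 4-fold higher. These were 1.84 with 8 genes and 1.202 with 4 genes under those scalings, and 2.08 with 10 genes for averaged probe sets. Cytokine receptors (1.49), lineage transcription factors (1.18), STAT5 and cytokine feedback (1.25), the classical dendritic cell core (1.11) and chemokine receptors (1.08) were also in the upper end, and stayed there after quantile normalization. With averaged probe sets the chemokine receptor list left it, at percentile 95.0. Inflammatory cytokines (1.16), MHC class II (1.07) and the markers of megakaryocytes (1.34) and of T and NK cells (1.13) were in the upper end and left it after quantile normalization, at percentiles 96.7, 95.1, 96.5 and 88.4. The megakaryocyte markers also left it with averaged probe sets, at percentile 97.26. The monocyte (0.13), cDC2 (0.37) and secondary granule (0.65) lists were in the lower end. With quantile normalization their medians were -0.37, -0.44 and -0.20, and the monocyte list stayed there at percentile 1.63 while the others left it at 2.84 and 15.3. With averaged probe sets the cDC2 list also left the lower end, at percentile 2.94, and the early progenitor, interferon response and cholesterol synthesis lists entered it, at 2.19, 0.6 and 0.25. Median centring takes 1 number off every gene of an array and left the percentiles of these lists as they were. As deposited, 1043 genes were counted, 929 higher and 114 lower. With quantile normalization it was 383 higher and 506 lower, and with median centring 155 higher and 411 lower. The lower and higher pseudocounts gave 2894 and 288 genes.

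Adherent cells of the GM-CSF culture were set against adherent cells of the M-CSF culture, 1 array each. Ccl17 and Ccl22, chemokine genes of alternatively activated macrophages and dendritic cells, read 1133 and 1661 with GM-CSF and 5.58 and 41.9 with M-CSF, log2 differences of 4.95 and 4.52. Arg1, the arginase gene, read 898 against 16.2 (4.27), Itgax, the CD11c gene, 4904 against 1083 (2.15), and Irf4 319 against 27.0 (2.57). M-CSF cultures had higher Hmga2, a chromatin protein gene (25.6 against 2451, -5.43), Folr2, a folate receptor gene of tissue macrophages (26.2 against 1529, -4.75), and Maf, a macrophage transcription factor gene (1063 against 4693, -2.11). Csf1r, the M-CSF receptor gene, read 8438 and 8426, and Zbtb46 66.8 and 33.5.

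Alternative activation genes had a median difference of 2.495, with 9 of 12 at least 4-fold higher with GM-CSF, and MHC class II genes one of 1.77; both lay above all random lists. Also above all random lists were cDC2 (1.04), costimulation (0.94), secondary granule (1.36), cytokine receptor (0.57) and lineage transcription factor genes (0.49). Classical dendritic cell core (0.35), STAT5 (0.55), chemokine receptor (0.37), immediate early (0.35), primary granule (0.31) and inflammatory cytokine genes (0.25) were in the upper end. Interferon response (-1.30), cell cycle (-0.80), plasmacytoid (-0.42) and macrophage genes (-0.26) were in the lower end. Rtp4, an interferon-induced gene, read 987 with GM-CSF and 3457 with M-CSF. The secondary granule genes include Mmp8, the neutrophil collagenase gene, at 6181 against 473. The mix of cells in each culture sample is not known here. A different mix and a difference within the same cells therefore cannot be told apart. In all 257 genes were counted, 203 higher and 54 lower with GM-CSF, against 502 with the lower and 120 with the higher pseudocount.

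Non-adherent CD11c+ cells of the GM-CSF culture were set against its adherent cells. Ccr7 read 7190.4 in the CD11c+ and 1007 in the adherent cells (log2 difference 2.80), Spib 1407 against 171 (2.83), and Il12b, a subunit gene of the cytokine IL-12, 2367 against 229 (3.20). Zbtb46 read 293 against 66.8 (1.72), Irf8 5181 against 2075 (1.31) and Flt3 204 against 21.03 (2.15), while Itgax, by whose product the CD11c+ cells were purified, read 4515 against 4904. Costimulation and maturation genes had a median of 2.06 with 11 of 20 at least 4-fold higher, and classical dendritic cell core genes one of 1.51 with 9 of 24; both lay above all random lists, as did STAT5 genes (0.79). Alternative activation (0.47), cDC2 (0.44) and MHC class II genes (0.31) were in the upper end.

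Granulocyte transcripts moved the other way: the secondary granule list had a median of -2.64, with 8 of 13 genes at least 4-fold lower in CD11c+ cells. Ngp, a neutrophil granule protein gene, read 123 against 4379, the lactoferrin gene Ltf 33.6 against 1337, and Prg2, an eosinophil granule gene, 4.29 against 850.5. Because the CD11c+ cells were purified by CD11c, removal of other cells and a difference within the same cells cannot be told apart in this comparison. Mast cell, basophil and eosinophil markers (-0.70), megakaryocyte markers (-0.30) and primary granule genes (-0.27) were likewise in the lower end. So were interferon response (-0.64), ribosome biogenesis (-0.53), cell cycle (-0.48), cholesterol synthesis (-0.30) and macrophage genes (-0.22). In all 127 genes were counted, 99 higher and 28 lower in CD11c+ cells, against 304 with the lower and 57 with the higher pseudocount.

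Monocytes given GM-CSF were followed at 0, 24 and 48 h, 1 array each. No monocytes kept in culture without GM-CSF were measured, so effects of GM-CSF and of time in culture cannot be told apart. Zbtb46 read 127.6, 1487 and 2155 at these times, with 1 of its 4 probe sets opposite in direction at 24 h, Itgax 59.3, 12043 and 12541, and Irf4 473, 6639 and 6248. Ciita read 63.0, 2368 and 3333, Ccl17 48.7, 16201 and 16325, and Mmp12, the macrophage elastase gene, 12.8, 13564 and 14573. Cish and Socs2, feedback inhibitor genes induced by STAT5, read 284, 9592 and 8989, and 26.6, 2665 and 6439. Irf8 read 10171, 1162 and 1791, Klf4 14857, 4006 and 4214, and Nr4a1, a nuclear receptor gene of monocytes, 5573, 73.0 and 54.2. Csf1r read 17455, 18097 and 17279.

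**Figure D4:**
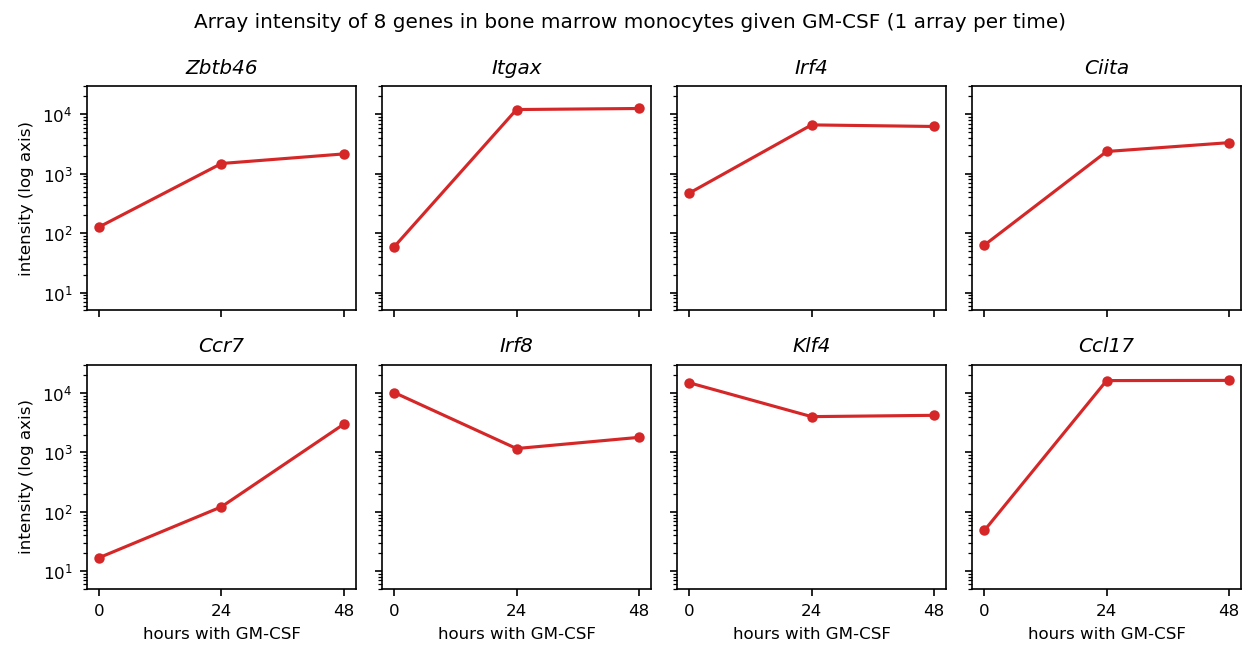
Intensity on a log axis of 8 genes in monocytes given GM-CSF for 0, 24 and 48 h, where each point is 1 array. Zbtb46, Itgax, Irf4, Ciita and Ccl17 lie higher at 24 h than at 0 h, Irf8 and Klf4 lie lower, and Ccr7 goes from 16.9 to 121 at 24 h and to 2977 at 48 h.

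At 24 and 48 h, alternative activation genes had median differences from 0 h of 3.32 and 2.92, MHC class II genes 2.39 and 3.20, costimulation genes 1.54 and 2.71, cDC2 genes 1.40 and 1.79, and classical dendritic cell core genes 0.81 and 1.60, all above every random list. STAT5 (1.45 and 1.21), cDC1 (0.59 and 0.52), cholesterol synthesis (0.85 and 1.25), lipid handling (0.55 and 0.94), inflammatory cytokine (0.68 and 0.87), ribosome biogenesis (0.85 and 0.39) and glycolysis genes (0.30 and 0.36) were in the upper end at both times. Cd36, a lipid scavenger receptor gene, read 91.2, 2116 and 6912. Primary granule (-2.11 and -2.42), cell cycle (-1.44 and -1.22), immediate early (-0.94 and -0.96), secondary granule (-0.54 and -0.45) and monocyte genes (-0.59 and -0.50) were in the lower end. Prtn3, the proteinase 3 gene, read 10005, 166 and 156, and Cx3cr1 2874, 48.2 and 45.1. Chemokine receptor genes were in the lower end at 48 h (-0.57). Erythroid markers were in the lower end at both times (-1.12 and -0.76), and megakaryocyte markers in the upper end at 48 h (0.52), with the platelet factor gene Pf4 at 50.3, 10082 and 8087.

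Between 24 and 48 h interferon response genes had a median difference of 1.42, after -2.21 between 0 and 24 h and -0.76 between 0 and 48 h. Rtp4 read 3523, 108 and 1649 at the 3 times. Costimulation (0.93), classical dendritic cell core (0.61), plasmacytoid (0.51), cholesterol synthesis (0.36) and cell cycle genes (0.20) were also in the upper end, and ribosome biogenesis (-0.41) and primary granule genes (-0.39) in the lower. Cd207, the langerin gene, read 23.2 at 24 h and 1569 at 48 h, and Cd83 435 and 5702. In all 710 genes were counted between 0 and 24 h (335 higher, 375 lower), 848 between 0 and 48 h (526 higher, 322 lower) and 137 between 24 and 48 h (all higher but 9). The last count was 223 with the lower and 65 with the higher pseudocount, and the higher one gave 555 between 0 and 48 h.

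The genes that set bone marrow pre-cDC apart from the earlier progenitors were followed in the cultures and monocytes, which share no array with them. The 535 genes higher in pre-cDC had a median of 0.14 in GM-CSF against M-CSF adherent cells, above all random lists. Of these, 328 lay above and 206 below 0. The 430 lower genes had a median of -0.19, below all random lists, with 138 above and 292 below 0. In CD11c+ against adherent cells the median of the lower genes was -0.25, below all random lists. That of the higher genes was 0.01 at percentile 94.5, inside the range of random lists, but 0.06 at percentile 98.0 for the 105 that differed at least 4-fold and 0.03 at percentile 99.6 with the mean of probe sets. In monocytes the higher genes had medians of -0.29 at 24 h and -0.15 at 48 h, and the lower genes 0.33 and 0.23, opposite to the pre-cDC direction. Between 24 and 48 h they were 0.16 and -0.11. With the 105 higher genes that differed at least 4-fold, the median at 48 h against 0 h was -0.02 at percentile 17.9, inside the range of random lists. With the 51 lower genes that differed at least 4-fold, the medians were 0.06 in GM-CSF against M-CSF cells and -0.27 and -0.38 in monocytes at 24 and 48 h, which turns the direction of the lower list in these 3 comparisons.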

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

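No alternative was added after the results were seen. Over all alternatives, the values of genes named in tested comparisons kept direction and side of the threshold in 5730 cases, lost the call in 117 and gained it in 15, and none reversed. Tested gene lists kept their state, called or not called, in 306 cases, lost the call in 65 and gained it in 1. Many kept states belong to lists that were never called, since the main setting called 67. Of the lost calls, 61 came with the estimated correlation, 3 with the mean of a gene's probe sets and 1 with the replicate block. Values of genes named in single-array comparisons moved by more than the replicate spread in 1104 cases and by less in 1752. Only the bone marrow progenitor groups had replicates, so this yardstick holds no spread of the culture, monocyte or Spl samples themselves. With every probe set on its own, which enlarges the number of features, 4967, 8986 and 9884 were called in GMP against CMP, CDP against GMP and pre-cDC against CDP, and 2035, 1151 and 1338 counted for the Spl array and for monocytes at 24 and 48 h against 0 h. A 2-fold minimum, a stricter criterion, left 406, 312, 798 and 1185 genes in GMP against CMP, CDP against CMP, CDP against GMP and pre-cDC against CDP. Leaving out one array each, where the lone array left in a group is assumed to vary like the other groups, gave 1831 to 3139 genes in GMP against CMP and 1602 to 2655 in CDP against CMP. The sample number as a replicate block gave 3382, 2938, 5360 and 6308 genes in the 4 comparisons, against 3075, 2611, 5115 and 6073 without it. With the block there were 66 list calls, against 67. Deviations with the same number correlated weakly across genes, at -0.02 to 0.18, so whether the number pairs the arrays stays open. Of the 67 list calls, 6 were kept with an estimated correlation. Calls were also lost by lists with an estimated correlation below the preset 0.01, so a lost call does not by itself show correlated genes. The limit of 4 degrees of freedom in that setting also raises the p-values, and the 2 effects were not separated.

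Pseudocounts set how dim genes count, and a lower or higher pseudocount gave, in this order, 1768 or 470 genes particular to pre-cDC, 2894 or 288 for the Spl array, 502 or 120 for GM-CSF against M-CSF adherent cells, 304 or 57 for CD11c+ against adherent cells, and 223 or 65 for monocytes at 48 against 24 h; for 48 against 0 h the higher one gave 555. Quantile normalization and a floor at the 75th percentile gave 70 and 87 genes for 48 against 24 h, and median centring gave 566 for the Spl array; the cause was not tested. On the Spl array quantile normalization turned the medians of the secondary granule, monocyte and cDC2 lists to -0.20, -0.37 and -0.44. Median centring turned these to -0.47, -0.98 and -0.75, and those of the classical dendritic cell core, MHC class II and chemokine receptor lists to -0.0017, -0.0396 and -0.0326; centring takes 1 number off every gene, so it left the percentiles of these lists unchanged and these signs do not place them against other genes. The lower pre-cDC genes that differed at least 4-fold had medians of 0.0633 in GM-CSF against M-CSF cells and -0.27 and -0.38 in monocytes at 24 and 48 h, each opposite to the longer list; the cause was not tested. No background was measured in the values used here, so how far it limits dim genes is not known.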

Other observations

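The tests of the cell cycle classes, of the erythroid genes and of the culture genes in monocytes were chosen only after the result was seen.

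The cell cycle list split by function between pre-cDC and CDP. Of 15 genes of DNA replication 13 fell in pre-cDC and 1 rose (median log2 difference -0.77), and of 16 genes of mitosis 14 rose and 0 fell (median 0.52). Fisher's exact test of class against direction over the called genes, two-sided, gave p = 7.48e-07, but the classes were drawn after the falls and rises were seen and the genes are not independent, so this p restates the split and is no evidence for it. Cycle phases were not measured here, and the cause of the split stays open.

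Genes that separated GM-CSF from M-CSF adherent cultures were looked up in monocytes given GM-CSF, which share no array with the cultures. The monocytes had no arm without GM-CSF, so a change in them cannot be credited to GM-CSF rather than to time in culture. The 203 genes higher with GM-CSF had a median difference of 0.90 in monocytes at 48 h against 0 h, above all 10000 matched random lists, with 79 of them at least 4-fold higher and 18 at least 4-fold lower. At 24 h the median was 0.77, also above all of them. The 54 genes lower with GM-CSF went both ways in monocytes: at 24 h 28 lay above and 26 below 0, with a median of 0.05 at percentile 68.6, and at 48 h 35 lay above and 19 below, with a median of 0.32 at percentile 99.97. As a set they were thus not lower in monocytes given GM-CSF at either time, which leaves open what single members do.

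Early erythroid genes were higher in CMP and GMP than in CDP. The largest difference of Hba-a1, Slc4a1 and Alas2, abundant in maturing red cells, was 0.091 on the log2 scale. Hba-a1 read 1 to 5.42 on the CMP, GMP and CDP arrays. These values argue against maturing red cells or their free RNA only as far as the probe sets of these genes track such RNA. That was not checked, and in monocytes Hba-a1 and Hbb-b2 went apart. Klf1, Epor, Car1, Car2 and Ermap, 5 of the 8 matched markers, picked after their values were seen, differed together between the 2 arrays of a group: all 5 in one direction in CMP (median 0.86, replicate 1 minus replicate 2) and all 5 in the other in GMP (median -0.89), in each case with 0.01 percent of random lists as far apart, the smallest share that 10000 draws can give. Because these genes were picked and then set against unselected lists, the share decides nothing. A number of early erythroid progenitors that differed between sorts and a programme that varies within the sorted cells themselves both remain open. How far the CD135+ gate of CMP and the CD16/32+ gate of GMP kept such progenitors out is not known here.

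On the Spl array most counted genes were higher than in bone marrow pre-cDC, and cell cycle genes were lower. After quantile normalization 43.1% of counted genes were higher, against 89.1% as deposited, but that step gives all arrays one distribution and would remove a real shift as well, so whether the scale and low end of this array account for the first pattern stays open. A scale difference is argued against for the cell cycle genes, whose median was -3.75 after quantile normalization and still below all random lists. Differences between the tissue or handling of that sample and bone marrow, or a wrong label, were not tested and remain open, as this is a single array whose labels differ from each other.

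Some values stand outside these groups. In monocytes given GM-CSF for 0, 24 and 48 h, Cdh1, the E-cadherin gene, read 24.1, 9789 and 9762, and Car2 341, 92.8 and 4038. Hba-a1, looked at after its values were seen, read 921, 1970.4 and 1492 on the same arrays, and Hbb-b2, whose probes may also bind related globin genes, 8388, 71.6 and 3.15; what separates the 2 globin genes was not tested.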
